A study of Rattus norvegicus with 4 samples.

How the data were processed

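Gene expression was measured in 4 cultures of rat cortical neurons on single-colour Agilent arrays. Per the labels' protocols, neurons came from Sprague Dawley embryos of embryonic day 18.5, were infected with a lentivirus carrying a control shRNA (shCTL) or an shRNA against Cmtr1 (shCM1) at day 2 in vitro, and were harvested at day 7. Total RNA was amplified and labelled with Cy3. Each group held 2 arrays, from 2 independent experiments per the series' design. The sample titles use a prefix of si where the shRNA field and the design use sh, and the groups were taken as the shRNA field gives them.

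The deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers. The intensity used was the processed signal, which the software had already background-corrected and which the authors had not normalized between arrays in these files. Each array held 45018 spots, of which 43379 were gene spots for 41012 probes. The probes well above background numbered 34439 and 36503 for shCTL replicates 1 and 2, and 35734 and 37068 for shCM1 replicates 1 and 2. No gene spot was saturated, and 86 to 98 gene spots per array carried an outlier mark and were left out. For arrays, the number of arrays limits the precision. The authors' value table of the whole series also holds linear intensity values, as deposited. Each of its columns correlated with its own array at 0.9998 or above on the log2 scale, with medians of 117.7 and 131.9 for shCTL and 117.6 and 132.0 for shCM1. The sorted values of columns from the same slide nearly coincided, while the step that made them is not given in the sources used here. This table was used only as an alternative.

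For the results, spots of a probe were averaged, log2 was taken and each array's 75th percentile over gene probes was subtracted. Probes well above background on at least 2 of the 4 arrays were kept, which left 36701 probes. A gene was represented by its probe with the highest mean signal, giving 30151 genes, of which 15595 had a gene symbol. Other probes are given where they differ by more than 1.5 times from it for a named gene that passed. Probes were named through a RefSeq gene table of assembly GRCr8, where 19189 matched by accession, 2995 by symbol, 203 by an older symbol and 1026 by description. The file's own name was kept for 17599 probes. Probes of near-identical genes, such as the Fc gamma receptors, haemoglobins, histones and olfactory receptors, can share signal, and those names are uncertain.

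The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A fit with the slide as a block was made beside it. Its variance prior held 18.18 degrees of freedom, so its p rests mostly on the spread of genes of like brightness. A gene can thus pass although its 2 slides differ. Replicate 1 of both groups was on 1 slide and replicate 2 of both on the other, each with its own scan, so slide, scan and replicate number are the same split. Deviations of same-numbered arrays from their group means correlated at 0.711 across genes. The leading principal component held 65.2% of the variance and separated the slides, and the next held 24.9% and separated the groups. The slide pairing comes from the file headers, and the labels do not state whether each slide holds 1 experiment. With 2 arrays against 2, an exact permutation test of a single gene cannot go below 0.33. A count of genes at least 1.5-fold apart in the same direction within both slides was made without a test.

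There were 22 gene lists and 10 cell type marker lists, fixed before the data were examined, and all 32 had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. With 4 arrays the last of these tests rest on few residual degrees of freedom. A list that they do not call is therefore not shown to be unmoved. After the results were seen, each list's median was also set against those of 10000 lists of other genes matched on brightness. The two-sided share at least as far out, adjusted by Benjamini-Hochberg over the 32 lists, is the adjusted share below, and 0.00128 is the smallest reached. It compares genes within these arrays and does not replace replicates. The named genes were also fixed by a rule set before the data were examined. It took Cmtr1, then Cmtr2, Camk2a, Camk2b, Rig1 (older symbol Ddx58), Ifih1, Ifnb1 and Isg15, then genes past the test without a block, 12 per direction. As none passed, each direction was filled with the 12 genes well above background on all arrays whose smaller within-slide difference was largest. Per list, up to 4 members past that test were named, or otherwise the 2 with the smallest p. Ifit1 was in the rule and was not analysed here. Some genes that these rules take are not reported here. Other genes named below were chosen after their values were seen, mostly because they passed the slide-blocked fit. A gene dim on every array of a group was given a bound, the mean of the brighter group against the lowest signal well above background, or its own signal where higher, and this bound holds for the 75th percentile scaling only. Where the gene's own signal was the higher on both arrays, the value is the plain estimate and not a bound.

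On simulated data built from the 30151 genes' levels, slide differences and trend in spread, the slide-blocked fit recovered 88% of 100 genes moved by 1 on the log2 scale and 100% of 100 genes moved by 2, with 3 false calls among 191. The fit without a block recovered 0% at either size. The simulated spread followed the fitted trend by construction, which favours the fit with the trend. A simulated list of 30 genes moved by 0.5 was called by camera at the preset correlation, while 0 of 50 unmoved lists were, and it was not called with an estimated correlation. The simulated noise was independent between genes and the unmoved lists were drawn at random. The 0 of 50 therefore does not give the rate of false calls for real lists, whose genes can vary together. For oxidative phosphorylation genes the estimated correlation was 0.49, against the preset 0.01. Alternatives covered background correction (normexp with an offset of 50), quantile normalization, the authors' table, the filter on dim probes, the variance prior, the block, the probe rule, the fold limit, the set test and leaving out each array. Where leaving out an array moved the difference of a named gene that had passed by more than 1.5 times, the value without it is given, with 1 array standing for its group. These fits had no block and leave the slides unequal between the groups, so such a value also takes in the slide difference. Cyclic loess, combinations of the block with other scalings or without the trend, and lists tested against genes with a symbol were added after seeing the data.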

Results

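The series measured gene expression in cultured rat cortical neurons after knockdown of CMTR1, the cap methyltransferase that methylates the ribose of the first transcribed nucleotide of an mRNA. The shCTL and shCM1 groups held 2 arrays each. The 75th percentile signal was 652.3 and 754.6 in shCTL replicates 1 and 2, and 596.3 and 743.8 in shCM1 replicates 1 and 2. Between 84.0% and 90.4% of probes were well above background. Levels below are log2 signals relative to the array's 75th percentile, and differences are shCM1 minus shCTL with the standard error of the fit without a block.

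The question of the series was how gene expression differs in neurons with less CMTR1. The shRNA sequences were not in the sources used. Effects of lower CMTR1 and off-target effects of the shRNA could therefore not be told apart in any difference below. Cmtr1 itself was at 27.7% of its control level, with a log2 difference of -1.85 (SE 0.22, n = 2 arrays per group). Its level was -1.43 and -1.86 in the shCTL arrays and -3.46 and -3.53 in the shCM1 arrays. Within the slides it was lower by log2 differences of -2.04 and -1.67. The adjusted p from limma was 1 without a block and 1.95e-07 with the slide as a block. The difference was -1.22 with normexp. The blocked adjusted p was 0.257 when the intensity trend was left out of the variance prior. Cmtr2, which methylates the second transcribed nucleotide, had a log2 difference of 0.30 (SE 0.20) and passed neither fit.

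Ccl3, an inflammatory chemokine, stood highest in the shCM1 arrays among the named genes, at 6.03-fold its control level (log2 difference 2.59, SE 0.42). Other genes of immune cells were also higher, among them Il1b at 3.32-fold, Fcgr3a at 3.24-fold, Lyz2 at 2.72-fold and Ccl4 at 2.55-fold. With normexp their log2 differences were smaller, 1.39 for Ccl3, 0.62 for Il1b, 0.50 for Fcgr3a, 0.94 for Lyz2 and 0.43 for Ccl4, and all 5 still passed with the block. Among the genes with the largest drops in both slides, beside Cmtr1, were Chst9 at 28.6% of control, Ccl20 at 30.2%, Pomgnt1 (an enzyme of protein O-mannosyl glycosylation) at 30.6%, Slc25a18 (a mitochondrial glutamate carrier) at 32.8% and Paox (polyamine oxidase) at 33.1%. These genes were picked for size in both slides. Chst9 had a log2 difference of -1.81, against -0.63 with normexp and -1.17 by its other probe. All of them passed the slide-blocked limma fit and none passed without the block. The remaining genes higher by that rule were Fcgr2a, Fyb1, Or14a257d, Fcgr2b, Susd3, Adrb3 and Fcgr2al1, with log2 differences from 1.20 to 1.48. With normexp Fcgr2a had 0.60, Fyb1 0.58, Or14a257d 0.45, Fcgr2b 0.39, Susd3 0.37 and Adrb3 0.71, and after cyclic loess with the block Fcgr2b (limma, adjusted p = 0.0592) and Susd3 (0.0745) did not pass. The remaining lower ones were Lcn2, Thsd4, Kpna1, Rsph10b, Tf and Gchfr, from -1.40 to -1.21, with Thsd4 at -0.52 and Rsph10b at -0.53 under normexp. Thsd4 had -0.76 without shCTL replicate 1. Thsd4 had -0.72 without shCM1 replicate 2.

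**Figure D1:**
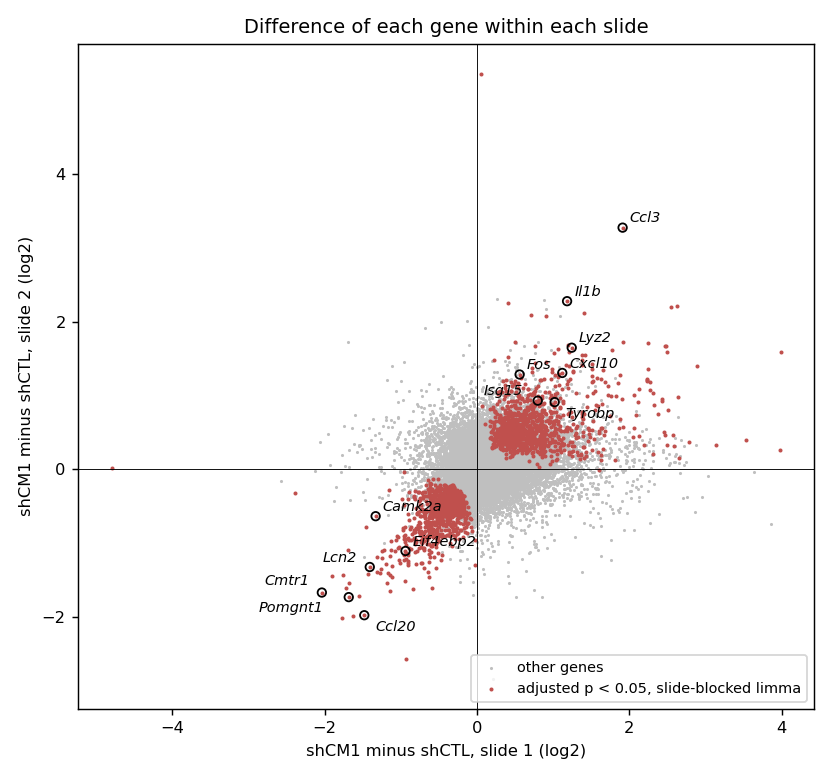
Each point is a gene, with its shCM1 minus shCTL difference on slide 1 (horizontal, log2) against slide 2 (vertical, log2). Red points passed the slide-blocked limma fit, and Cmtr1 lies at -2.04 and -1.67, Ccl3 at 1.91 and 3.27.

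Across all genes, limma without a block called 0 of 30151 genes, with 902 at an unadjusted p under 0.05. These 902 are a smaller share than the 0.05 that genes without any difference would give. With the slide as a block it called 1995, of which 1087 were higher and 908 lower. The block without the intensity trend called 0, with 5054 at an unadjusted p under 0.05. The split by direction depended on the scaling: the blocked fit called 344 higher and 554 lower after quantile normalization, 246 and 442 after cyclic loess, 237 and 427 in the authors' table, and 563 and 758 with normexp. In all 5 scalings 593 genes were called, 216 higher and 377 lower. At least 1.5-fold in the same direction within both slides, 543 genes were higher and 189 lower, against 195 and 301 after quantile normalization and 38 and 109 with normexp. The other ways of pairing the arrays gave 98 such genes for the crossed split and 3484 for slide 2 against slide 1. The differences of slides 1 and 2 correlated at 0.358 across genes, which are not independent replicates.

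Microglial markers were higher in the shCM1 arrays. Of 19 measured, 17 were higher within both slides, with a median log2 difference of 0.67 (0.62 and 0.48 within the slides). In the slide-blocked fit 8 rose and none fell, and adjusted over the list alone 13 rose. Lyz2 (lysozyme) had a log2 difference of 1.45 (SE 0.23), Aif1 1.30 (SE 0.42), Cd14 1.02 (SE 0.22), Fcer1g 1.01 (SE 0.27) and Tyrobp 0.97 (SE 0.20). With normexp Aif1 had 0.42 and Cd14 0.53, and another probe of Tyrobp had 0.41. Aif1 had 0.81 without shCM1 replicate 1. Laptm5 had 0.19 and did not pass. The exceptions to the common direction were C1qb, with 0.09 and -0.21 within the slides, and Cd74, with 0.25 and -0.32. Camera called the list with an adjusted p of 1.97e-08 (7.18e-09 with the block), and the adjusted p was 0.363 with an estimated correlation. The adjusted share against brightness-matched lists was 0.00128.

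Inflammatory genes went in both directions. In the slide-blocked fit 4 of 27 rose and 5 fell, and adjusted over the list alone 6 rose and 6 fell. The cytokines Il1b (1.73, SE 0.65) and Il1a (1.51, SE 0.51) and the chemokines Ccl3 and Ccl4 rose, and these are products of activated microglia and macrophages. With normexp Il1a had 0.44. Ccl20 (-1.73, SE 0.30), Lcn2 (-1.36, SE 0.21), Ccl2 (-1.23, SE 0.32), complement C3 (-1.02, SE 0.31) and Icam1 (-0.48, SE 0.19) fell. Il1b had 2.64 and Icam1 -0.31 without shCTL replicate 1. Il1b had 0.82, Ccl2 -0.79 and C3 -0.58 without shCTL replicate 2. Il1a had 0.88 without shCM1 replicate 1. The call of Icam1 was lost after cyclic loess with the block, at an adjusted limma p of 0.0604. The list was not called by camera (adjusted p = 0.720), whose direction was lower while the median was 0.07 and the mean 0.15.

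Among 49 interferon-stimulated genes, 6 rose and 2 fell in the slide-blocked fit, and adjusted over the list alone 10 rose and 5 fell. Cxcl10 had a log2 difference of 1.21 (SE 0.25), Isg15 0.86 (SE 0.66), Rsad2 0.86 (SE 0.40), Tap1 0.69 (SE 0.28), Lgals3bp 0.60 (SE 0.16) and Isg20 0.59 (SE 0.34). Isg15 had 0.16, Rsad2 0.46 and Isg20 0.16 without shCTL replicate 1. Isg15 had 1.57, Tap1 0.39 and Isg20 1.02 without shCTL replicate 2. Isg15 had 1.63 without shCM1 replicate 1. Isg15 had 0.10, Rsad2 0.44 and Isg20 0.33 without shCM1 replicate 2. Within slides 1 and 2 Isg15 had 0.80 and 0.93, Rsad2 0.84 and 0.88, and Isg20 0.76 and 0.42. With normexp Rsad2 had 0.54 and Cmpk2 -0.46, and another probe of Rsad2 had 0.49. Cmpk2 (-0.69, SE 0.20) and Gbp2 (-0.37, SE 0.18) fell, and Gbp2 passed under none of the other scalings. The list as a whole was not called (camera adjusted p = 0.365, and 0.198 with the block). It was called higher without shCTL replicate 2 (adjusted p = 0.0162), and its direction turned without shCTL replicate 1 (0.455). Its median was 0.20 on slide 1 and 0.03 on slide 2. Ifnb1, the gene of interferon beta, had a difference of 0.46 (SE 0.32) and passed neither fit.

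The cytosolic RNA sensors did not pass. Rig1 had a log2 difference of 0.13 (SE 0.21), with -0.07 and 0.34 within the slides, and Ifih1 had -0.29 (SE 0.38). Tlr3, an endosomal sensor of double-stranded RNA, had 0.58 (SE 0.25). Zbp1 was not well above background in the shCTL arrays. By the 75th percentile scaling it was 1.97-fold higher in shCM1 (log2 difference 0.98, SE 0.38), with an adjusted limma p of 0.0982 in the blocked fit. Its own shCTL signals entered that figure, so it is the estimate itself and not a lower bound. The log2 difference of Zbp1 was 0.70 after quantile normalization and 0.18 with normexp, so its size depends on the scaling. Of the 19 RNA-sensing genes 1 passed the blocked fit, over the list alone as well, Trim25, with -0.51 (SE 0.36). Of the other scalings Trim25 passed only with quantile normalization (limma, adjusted p = 0.0411, 0.0608 after cyclic loess). Trim25 had -0.97 without shCTL replicate 1. Trim25 had -0.06 without shCTL replicate 2. Trim25 had -0.28 without shCM1 replicate 1. Camera did not call the list (adjusted p = 0.543) but called it higher without shCTL replicate 2 (0.0468). Of 20 cap enzymes and cap-binding proteins, only Cmtr1 and Eif4g1 (-0.39, SE 0.24) fell in the blocked fit. Over the list alone these 2 also fell. The other 2 probes of Eif4g1 had -0.18 and -0.20. Eif4g1 did not pass with the block after quantile normalization (limma, adjusted p = 0.103), after cyclic loess (0.126) or in the authors' table (0.130). Eif4g1 had -0.69 without shCTL replicate 1. Eif4g1 had -0.09 without shCTL replicate 2. That list was not called (adjusted p = 0.161), with a median of 0.03, a mean of -0.08 and a lower direction by the test.

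Camk2a, a subunit of the synaptic calcium/calmodulin kinase CaMKII, was at 50.6% of control with a log2 difference of -0.98 (SE 0.23). Its differences were -1.33 and -0.64 within the slides, and the adjusted limma p was 4.44e-04 with the block. A second probe of Camk2a had -0.26. Camk2b had -0.11 (SE 0.13), with probes from -0.14 to 0.34, and passed neither fit. Of 29 genes of CaMK and calcium signalling, 22 were lower within both slides and 3 higher, with a median of -0.18 (-0.18 and -0.23 within the slides). In the blocked limma fit 8 fell and 1 rose. Beside Camk2a, Camk1d (-0.89, SE 0.25) and the calcineurin subunit Ppp3cb (-0.82, SE 0.29) fell, and the calmodulin-binding Pcp4 (0.50, SE 0.25) rose. Camk1d had -0.58 and Pcp4 0.30 without shCTL replicate 2. Pcp4 had 0.21 without shCM1 replicate 1. Ppp3cb had -0.43 and Pcp4 0.79 without shCM1 replicate 2. Adjusted over the list alone 12 fell and 1 rose. Camera called the list (adjusted p = 3.22e-08, 8.83e-09 with the block), with an adjusted p of 0.363 with an estimated correlation. The adjusted share against brightness-matched lists was 0.00128.

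**Figure D2:**
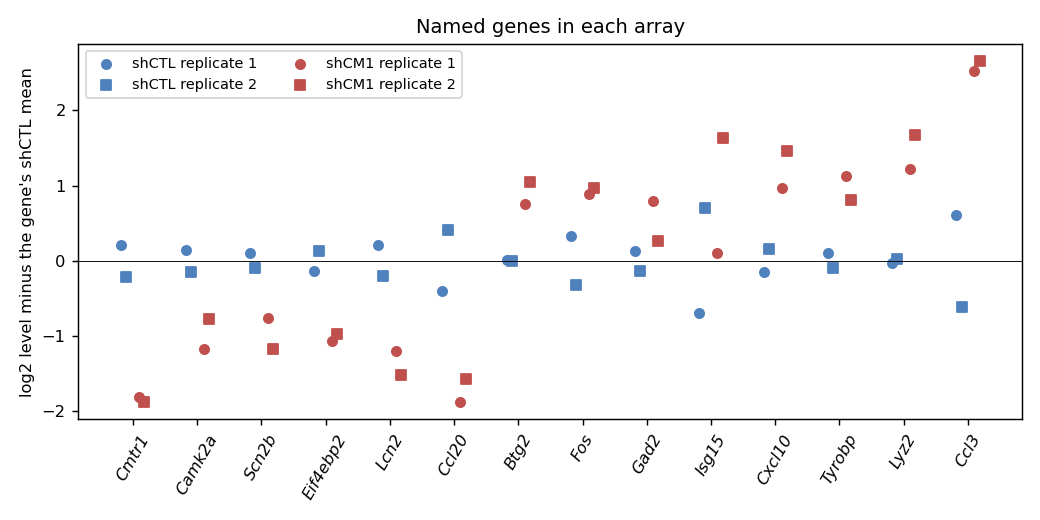
Log2 level of 14 named genes in each array, minus the gene's mean in the shCTL arrays (vertical axis), in blue for shCTL and red for shCM1, with circles for replicate 1 and squares for replicate 2. Both shCM1 arrays lie below 0 for Cmtr1 and Camk2a and above 0 for Ccl3 and Lyz2.

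Inhibitory neuron markers were higher in the shCM1 arrays, with a median log2 difference of 0.40 over 15 genes (0.36 and 0.40 within the slides). In the blocked fit 7 rose and 0 fell, and adjusted over the list alone 9 rose and 1 fell. The homeobox gene Dlx5 had 0.58 (SE 0.22), the GABA-synthesising enzymes Gad2 0.53 (SE 0.23) and Gad1 0.52 (SE 0.36), Dlx1 0.44 (SE 0.18), Erbb4 0.41 (SE 0.16) and Vip 0.40 (SE 0.35). After cyclic loess with the block Dlx1 (limma, adjusted p = 0.0664) and Erbb4 (0.0581) did not pass. Gad1 had 0.87 and Vip 0.79 without shCTL replicate 1. Dlx5 had 0.35, Gad1 0.17 and Vip 0.01 without shCTL replicate 2. Gad2 had 0.26, Gad1 0.12 and Vip 0.04 without shCM1 replicate 1. Gad1 had 0.92 and Vip 0.75 without shCM1 replicate 2. Within slides 1 and 2 Gad1 had 0.57 and 0.46, and Vip 0.36 and 0.43. The list was called by camera (adjusted p = 0.0110, 5.97e-05 with the block), with an adjusted p of 0.538 with an estimated correlation and an adjusted share of 0.00128 against brightness-matched lists. Without the block the list's call was lost when shCTL replicate 2 (adjusted p = 0.736) or shCM1 replicate 1 (adjusted p = 0.527) was left out.

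Excitatory neuron markers went in both directions. Rorb (-0.89, SE 0.24), Neurod6 (-0.62, SE 0.20) and Camk2a were among the 4 markers that fell in the blocked fit, and Bcl11b (0.48, SE 0.16), also expressed in interneurons, rose. Slc17a7, the vesicular glutamate transporter, had -0.01 (SE 0.20) and Neurod2 0.14 (SE 0.18), and neither passed. Adjusted over the list alone 5 of 14 fell and 1 rose. The median was -0.02, with -0.20 and 0.02 within the slides. Camera called the list lower (adjusted p = 0.00283, 0.00331 with the block), with an adjusted p of 0.363 with an estimated correlation. The call was lost after quantile normalization (adjusted p = 0.0542), in the authors' table (0.0680) and without shCM1 replicate 1 (0.0923), and with the block also after cyclic loess (0.0900). Averaged over the slides, the list's median did not stand apart from brightness-matched lists, with an adjusted share of 0.898. The slides differed in this, as 0.02% of matched lists were as low on slide 1 and 70.86% on slide 2, without adjustment.

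GABA signalling genes had a median of 0.14 over 24 genes, with 3 higher and 1 lower in the blocked fit and as many adjusted over the list alone. The adjusted share against brightness-matched lists was 0.00533. The receptor subunit Gabrd (0.64, SE 0.21), Gad1 and Gad2 rose. Camera did not call this list (adjusted p = 0.251, 0.0638 with the block) but called it higher after quantile normalization (adjusted p = 0.00422), without shCTL replicate 1 (0.0397) and without shCM1 replicate 2 (0.00524). No glutamate receptor gene passed the blocked fit among 31, over all genes or over the list alone. Grik3 had 0.35 (SE 0.19) and Grin2a 0.26 (SE 0.18), and camera did not call the list (adjusted p = 0.428), whose test pointed lower while the median was 0.01 and the mean 0.03.

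The 4 lists of neuronal channels, synapses and cytoskeleton had small medians, at -0.05 for voltage-gated channels, -0.03 for presynaptic genes, -0.07 for dendrite and cytoskeleton genes and -0.02 for postsynaptic scaffold genes. Postsynaptic medians were -0.04 and 0.04 within the slides. Averaged over the slides, none of the 4 medians stood apart from brightness-matched lists, with adjusted shares of 0.193, 0.424, 0.461 and 0.898. Within slides 1 and 2 taken singly, 2.26% and 1.05% of matched lists were as low as the presynaptic list, without adjustment. For the other lists these shares ran from 7.32% to 90.94%. Among 46 voltage-gated channel genes 5 fell and 1 rose in the blocked fit, and over the list alone 7 fell and 3 rose. The sodium channel subunit Scn2b (-0.97, SE 0.21) fell, and Kcna1 (0.49, SE 0.15) rose. Among 46 presynaptic genes 5 fell and 1 rose, over the list alone as well, with Nsf (-0.75, SE 0.32), Sh3gl2 (-0.57, SE 0.22) and Doc2b (-0.53, SE 0.18) among those that fell, while the vesicle protein Sv2c rose (0.58, SE 0.27). Among 44 dendrite and cytoskeleton genes 7 fell and 1 rose, and over the list alone 12 fell and 1 rose. Kif5a (-0.53, SE 0.18) and Gap43 (-0.45, SE 0.13) fell. Marcks (0.32, SE 0.12) rose by its brightest probe only, with -0.06, 0.08 and -0.01 for the others. Of 39 postsynaptic scaffold genes 3 fell, Baiap2 (-0.36, SE 0.14), Dlg3 (-0.34, SE 0.16) and Nlgn1 (-0.30, SE 0.16), over the list alone as well. After cyclic loess with the block Doc2b (limma, adjusted p = 0.0541), Sv2c (0.134), Baiap2 (0.104), Dlg3 (0.127) and Nlgn1 (0.163) did not pass. Nlgn1 had -0.19 without shCTL replicate 2. Nsf had -1.15 and Sv2c 0.31 without shCM1 replicate 1. Nsf had -0.36 and Sh3gl2 -0.38 without shCM1 replicate 2. With normexp Sv2c had 0.37. Another probe of Dlg3 had -0.16, and the other 2 of Doc2b had -0.35 and -0.39. Camera called all 4 lists lower without a block, with adjusted p of 0.00270, 0.00365, 5.12e-05 and 0.0443 in that order. With the block the adjusted p were 0.00331, 0.00331, 7.58e-06 and 0.0580, and with an estimated correlation they lay between 0.363 and 0.5003. After quantile normalization camera called none of the 4, with adjusted p of 0.143, 0.136, 0.136 and 0.714. With normexp it called all 4, with adjusted p from 1.22e-05 to 0.0214. The calls were also lost when some single arrays were left out, which leaves the slides unequal between the groups.

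Immediate early genes, which neurons transcribe within minutes of activity, were higher. The median log2 difference was 0.30 over 33 genes (0.27 and 0.33 within the slides), and 23 were higher within both slides against 2 lower. In the blocked fit 11 rose and 1 fell, and adjusted over the list alone 19 rose and 1 fell. Fos had 0.92 (SE 0.25), Btg2 0.90 (SE 0.17), Gadd45g 0.85 (SE 0.33), Junb 0.75 (SE 0.28), Arc 0.67 (SE 0.30) and Bdnf 0.59 (SE 0.30). Arc had 1.08 without shCTL replicate 1. Fos had 0.60, Junb 0.41 and Arc 0.25 without shCTL replicate 2. Gadd45g had 1.31 and Bdnf 0.21 without shCM1 replicate 1. Gadd45g had 0.38 and Bdnf 0.97 without shCM1 replicate 2. With normexp Junb had 0.48. Npas4 was not well above background in the shCTL arrays and was at least 2.32-fold higher in shCM1 by the 75th percentile scaling, with an adjusted limma p of 0.0309 with the block. Its log2 difference was 1.07 after quantile normalization and 0.25 with normexp, so that bound does not hold across scalings. Inhba fell (-0.55, SE 0.18). The list was called by camera (adjusted p = 5.12e-05, 4.46e-06 with the block), with an adjusted p of 0.363 with an estimated correlation and an adjusted share of 0.00128 against brightness-matched lists. Of these genes, Junb, Arc, Inhba, Npas4 and Bdnf did not pass after quantile normalization with the block.

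Among 35 genes of the integrated and unfolded protein stress responses 7 rose and 1 fell in the blocked fit, and over the list alone 10 rose and 2 fell. Atf3 had 1.29 (SE 0.41), with 2.13 on slide 1 and 0.45 on slide 2, Ddit4 had 0.77 (SE 0.19) and Aldh1l2 0.58 (SE 0.25), while Phgdh, an enzyme of serine synthesis, fell (-0.26, SE 0.16). Among 31 genes of the p53 pathway and apoptosis 5 rose and 1 fell, and over the list alone 7 rose and 4 fell. Cdkn1a, an inhibitor of the cell cycle, had 0.58 (SE 0.20), and Ccng1 0.42 (SE 0.14), while Zmat3 fell (-0.34, SE 0.13). Phgdh had -0.40 without shCTL replicate 1. Aldh1l2 had 0.30 and Phgdh -0.12 without shCTL replicate 2. Atf3 had 0.75 and Phgdh -0.15 without shCM1 replicate 1. Cdkn1a had 0.39 without shCM1 replicate 2. Phgdh had -0.17 in the authors' table. After cyclic loess with the block Atf3 (limma, adjusted p = 0.0722), Phgdh (0.231) and Zmat3 (0.114) did not pass. Against brightness-matched lists the adjusted shares were 0.0535 for the stress list and 0.0435 for the p53 list. Camera called neither list (adjusted p = 0.318 and 0.137, and 0.122 and 0.0823 with the block). Both were called higher after quantile normalization, each with an adjusted p of 0.00847, and the stress list also without shCM1 replicate 2 (8.39e-06). The medians were 0.22 and -0.08 within the slides for the stress list and 0.16 and 0.11 for the p53 list.

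Genes named as translation factors were lower, with a median of -0.11 over 61 genes (-0.09 and -0.10 within the slides). The list was taken by gene name, so it also holds regulators such as the repressor Eif4ebp2. In the blocked fit 4 fell and 0 rose, and over the list alone 6 fell. These were Eif4ebp2, a repressor of cap-dependent translation, with -1.02 (SE 0.17), the elongation factor Eef2 with -0.58 (SE 0.16), Eif4g1 and Eif3l (-0.36, SE 0.15). With the block Eif3l did not pass after quantile normalization (limma, adjusted p = 0.0625), after cyclic loess (0.0802) or in the authors' table (0.0737), and Eif4g1, whose other probes had -0.18 and -0.20, was lost in the same 3. By camera the list was called (adjusted p = 1.49e-07, 2.27e-07 with the block), with an adjusted p of 0.363 with an estimated correlation and an adjusted share of 0.0213 against brightness-matched lists. Ribosomal protein genes had a median of -0.03 over 79 genes, Rpl28 -0.21 (SE 0.13, another probe 0.03) and Rpsa -0.18 (SE 0.14). Of them 1 fell in the blocked fit, Rps26 (-0.49, SE 0.71), and 0 over the list alone. Within the slides Rps26 differed unequally, by -0.02 on slide 1 and -0.95 on slide 2. Rps26 had 0.06 without shCTL replicate 1. Rps26 had -1.03 without shCTL replicate 2. Rps26 had -1.50 without shCM1 replicate 1. Rps26 had 0.52 without shCM1 replicate 2. Camera called them lower (adjusted p = 0.00185, 0.00156 with the block, 0.5003 with an estimated correlation), but higher after cyclic loess, with an adjusted p of 0.00463. The lower call, without cyclic loess, was lost when shCTL replicate 1 (0.241) or shCM1 replicate 2 (0.381) was left out, and after quantile normalization (0.685). The adjusted share of the ribosomal list was 0.266.

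Lists of metabolism and maintenance had medians between -0.12 and -0.04. Against brightness-matched lists the adjusted share was 0.00731 for oxidative phosphorylation and 0.0152 for histones. It was 0.193 for heat shock genes, 0.870 for oxidative defence, 0.193 for glycolysis and 0.266 for cholesterol synthesis, so these 4 medians, averaged over the slides, did not stand apart. In the blocked fit 9 of 80 nuclear genes of oxidative phosphorylation, 6 of 26 of glycolysis, 3 of 25 of cholesterol synthesis, 2 of 23 heat shock genes and 2 of 35 histone genes fell, and 0 rose. Over the list alone 9, 10, 4, 3 and 8 fell in that order, and 1 glycolysis gene rose. Of 29 oxidative defence genes 3 fell and 1 rose, over the list alone as well. Ndufa5 had -0.30 (SE 0.13), the glucose transporter Slc2a1 -0.52 (SE 0.17) and the monocarboxylate transporter Slc16a7 -0.40 (SE 0.16). Acat2 (-0.44, SE 0.16, with a further probe at 0.54), Hmgcs1 (-0.31, SE 0.16) and Nsdhl (-0.37, SE 0.20) fell, and Mvd had -0.27 (SE 0.14). Gsta1 (-0.89, SE 0.39), Gstp1 (-0.36, SE 0.16) and Pgd (-0.36, SE 0.14, another probe 0.10) fell and Srxn1 (0.70, SE 0.56) rose. Hsph1 had -0.34 (SE 0.16) and Dnaja1 -0.28 (SE 0.14). The histone genes that fell were H2bc12 (-0.42, SE 0.60) and Hist1h4m (-0.40, SE 0.42). Hist1h2ac had -0.22 (SE 0.16) and Hist1h2af -0.18 (SE 0.13), and neither passed. Gsta1 had -1.39, Srxn1 -0.09, Hmgcs1 -0.18, H2bc12 -1.15 and Hist1h4m -0.94 without shCTL replicate 1. Gsta1 had -0.39, Gstp1 -0.21, Srxn1 1.49, H2bc12 0.32 and Hist1h4m 0.13 without shCTL replicate 2. Gsta1 had -0.59, Nsdhl -0.58, H2bc12 0.21 and Hist1h4m -0.04 without shCM1 replicate 1. Srxn1 had 0.36, Hmgcs1 -0.16, Nsdhl -0.15, H2bc12 -1.04 and Hist1h4m -0.77 without shCM1 replicate 2. With normexp Srxn1 had 0.31. Another probe of Hmgcs1 had -0.10 and another of Nsdhl -0.21. Of the genes named here that fell or rose, only Acat2 and Gsta1 passed with the block after cyclic loess, and the others had an adjusted limma p from 0.0648 for H2bc12 to 0.219 for Dnaja1. Camera called all 6 lists lower, with adjusted p from 1.97e-08 for oxidative phosphorylation to 0.00451 for oxidative defence. With the block they ran from 7.86e-10 to 0.00471, and with an estimated correlation from 0.363 to 0.538. After cyclic loess camera called none of the 6 without the block, with adjusted p from 0.125 to 0.682, and with the block histones only (0.0267). Oxidative phosphorylation was called after quantile normalization (0.0267, 0.0168 with the block) and in the authors' table (0.0355, 0.0145 with the block). After quantile normalization heat shock (0.0542) and histone genes (0.143) were called with the block only (0.0418 and 0.0196), as in the authors' table, and the other 3 lists in neither. With normexp all 6 were called. Without shCTL replicate 2 the histone and oxidative defence calls were lost (each 0.576), as without shCM1 replicate 1 (each 0.446). Those of oxidative phosphorylation and cholesterol synthesis were lost without shCTL replicate 1 (0.0577 and 0.609) and without shCM1 replicate 2 (0.127 and 0.381).

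**Figure D3:**
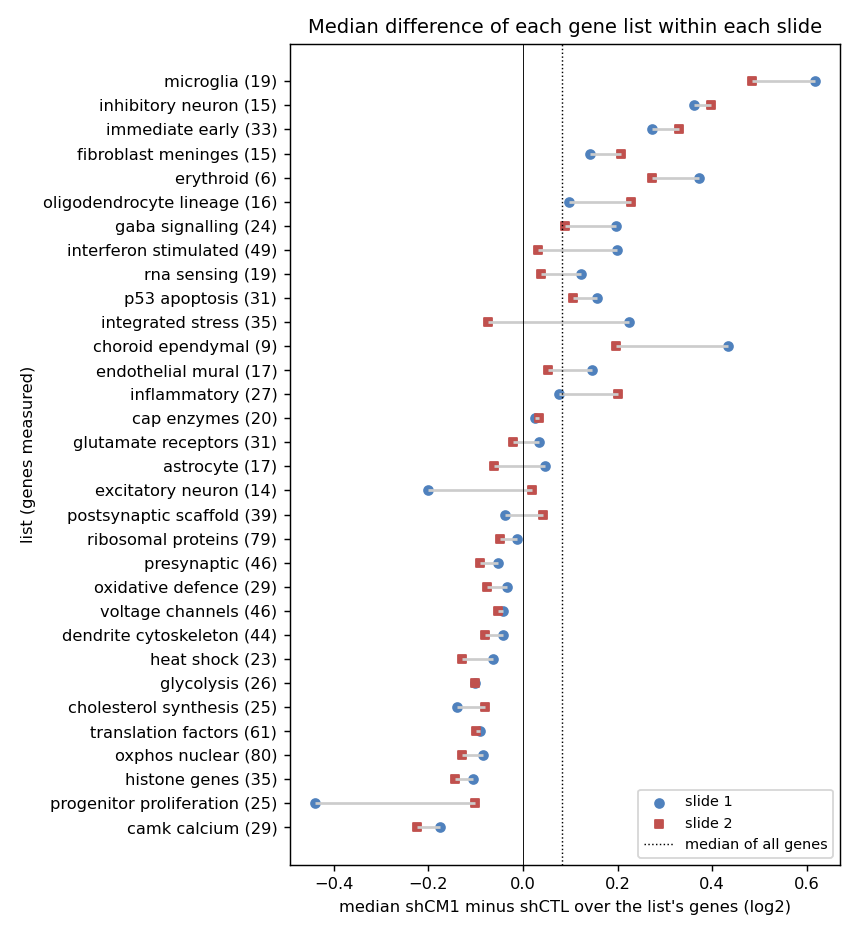
Median shCM1 minus shCTL difference (log2, horizontal axis) of each list's measured genes, in blue circles for slide 1 and red squares for slide 2, with the number of genes in brackets and the median of all genes, 0.08, as a dotted line. Microglial markers lie furthest right, at 0.62 and 0.48.

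Of the other cell types, astrocyte markers had a median of -0.01 over 17 genes. Agt rose in the blocked fit (0.62, SE 0.41), Gjb6 had 0.28 (SE 0.27), and over the list alone Agt alone passed. The list was not called (adjusted p = 0.561), and its test pointed lower while the mean was 0.04. It was called lower without shCTL replicate 1 (0.00102) or shCM1 replicate 2 (0.00524) and higher without shCTL replicate 2 (0.0468). Oligodendrocyte lineage markers had a median of 0.16 over 16 genes, where 2 rose, among them Mbp (0.52, SE 0.17), and Cspg4 (-0.35, SE 0.18) fell, over the list alone as well, and the list was called higher without shCM1 replicate 1 (0.00358). Fibroblast and meningeal markers had a median of 0.23 over 15 genes, where Dcn (0.86, SE 0.48) and Col1a2 (0.54, SE 0.19) rose and Vtn had 0.59 (SE 0.30), with 4 higher over the list alone, and the list was called higher without shCM1 replicate 1 (0.0286). Endothelial and mural markers had a median of 0.07 over 17 genes, where Pdgfrb (0.62, SE 0.52) rose, Abcc9 (-1.04, SE 0.34) and Cspg4 fell, and Cldn5 had 0.71 (SE 0.30). With normexp Abcc9 had -0.24 and did not pass with the block (limma, adjusted p = 0.154). Over the list alone 2 rose and 3 fell, and the test pointed lower while the mean was 0.03. Choroid plexus and ependymal markers had 0.09 over 9, with Clic6 at 0.59 (SE 0.26) and Aqp1 at 0.43 (SE 0.20), and 1 passed over the list alone against 0 over all genes. Erythroid markers had 0.21 over 6, with Hbb-b1 at 1.01 (SE 0.47) and Hbb at 1.26 (SE 0.57), which was well above background in 1 of 2 shCTL arrays, and these 2 rose, over the list alone as well. Hbb had 0.35 with normexp, where camera called the erythroid list higher (0.0294, 0.0123 with the block). Mbp (limma, adjusted p = 0.101), Cspg4 (0.114), Col1a2 (0.0768), Pdgfrb (0.145) and Hbb (0.121) did not pass with the block after cyclic loess. Agt had 0.13, Dcn 0.37, Pdgfrb -0.10, Hbb-b1 0.48 and Hbb 0.56 without shCTL replicate 1. Agt had 1.10, Dcn 1.35, Cspg4 -0.23, Pdgfrb 1.34, Hbb-b1 1.53 and Hbb 1.97 without shCTL replicate 2. Agt had 0.99, Dcn 1.41, Cspg4 -0.20 and Pdgfrb 0.97 without shCM1 replicate 1. Agt had 0.24, Dcn 0.31, Pdgfrb 0.27 and Hbb-b1 0.51 without shCM1 replicate 2. With normexp Mbp had 0.34, and its other probe had 0.17. By the scaling used camera called none of these lists, with adjusted p from 0.161 to 0.561, and from 0.0505 to 0.642 with the block.

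Markers of progenitors and proliferation had a median of -0.17 over 25 genes, with -0.44 on slide 1 and -0.10 on slide 2. In the blocked fit 6 fell and 2 rose, and over the list alone 11 fell and 3 rose. The mitotic genes Cdk1 (-0.51, SE 0.25), Ccnb1 (-0.45, SE 0.18) and Birc5 (-0.44, SE 0.27) fell, Mcm3 had -0.42 (SE 0.20), and the stem cell factors Sox2 (0.44, SE 0.36) and Hes5 (0.85, SE 0.77) rose. Birc5 had -0.69, Sox2 0.09 and Hes5 0.36 without shCTL replicate 1. Birc5 had -0.19, Sox2 0.80 and Hes5 1.34 without shCTL replicate 2. Cdk1 had -0.19, Birc5 -0.17, Sox2 0.84 and Hes5 1.97 without shCM1 replicate 1. Cdk1 had -0.83, Birc5 -0.71, Sox2 0.05 and Hes5 -0.27 without shCM1 replicate 2. Within slides 1 and 2 Cdk1 had -0.71 and -0.31, Birc5 -0.46 and -0.42, Sox2 0.41 and 0.48, and Hes5 0.22 and 1.48. Another probe of Ccnb1 had -0.19. After cyclic loess with the block Cdk1 (limma, adjusted p = 0.0684), Ccnb1 (0.0797), Birc5 (0.0547) and Hes5 (0.138) did not pass. Camera called the list lower (adjusted p = 5.12e-05, 1.49e-04 with the block), with an adjusted p of 0.504 with an estimated correlation and an adjusted share of 0.00128 against brightness-matched lists. Without shCM1 replicate 1 the direction was reversed, with an adjusted p of 0.758.

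Of the 32 lists, camera called 3 higher and 15 lower at the preset correlation, 17 with the block, and 0 with an estimated correlation or by fry. The setting with an estimated correlation cannot decide on the lists, as it also missed the simulated list moved by 0.5. The CaMK and calcium list lost its call there although its estimated correlation of -0.03 lay below the preset 0.01. The differences depended on brightness. Over 4 classes of equal size, from the dimmest to the brightest genes, the median was 0.26, 0.16, 0.06 and -0.05, and the same order held within both slides. The median of all genes was 0.08, and 0.01 after quantile normalization. After quantile normalization 6 lists were called higher and 4 lower. Of 161 genes, those of the naming rule and those added to it, 135 passed the blocked fit and 88 of these passed it under all 4 other scalings too. Among the 11 that passed under none of the others were Mbp, Cspg4, Ccnb1, Npas4, Bdnf, Hsph1, Nlgn1, Rps26, Srxn1 and Sv2c. Of the 135, the difference moved by more than 1.5 times or turned for 29 with normexp, and for 62 when 1 array was left out. It did so for 30 and 39 without shCTL replicates 1 and 2, and for 37 and 33 without shCM1 replicates 1 and 2.

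**Figure D4:**
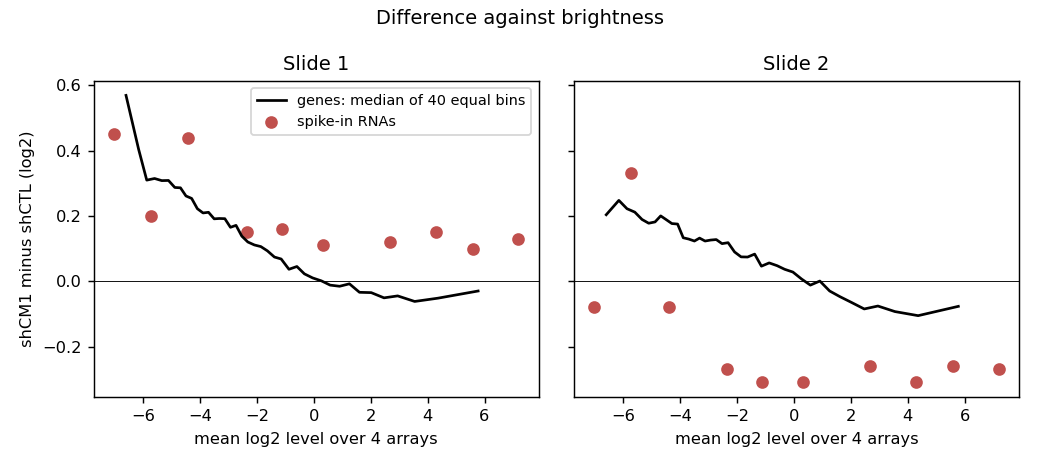
The black line gives the median shCM1 minus shCTL difference (log2, vertical axis) of genes in bins of equal size against their mean log2 level (horizontal axis), for slide 1 on the left and slide 2 on the right, and the red points are the 10 spike-in RNAs. In both panels the line lies higher for dim genes than for bright ones.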

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

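The fits with cyclic loess, with the block in another scaling or without the intensity trend, and with genes that have a symbol only were chosen after seeing the data. The Cmtr1 knockdown held its direction under each alternative run, with log2 differences from -2.067 to -1.638 when each array was left out and -1.974 after quantile normalization or loess, -1.982 in the authors' table and -1.223 with normexp. It passed limma with the replicate block (-1.852, adjusted p 1.95e-07), also after quantile normalization (8.63e-05), loess (0.000579), in the authors' table (0.00056) and with normexp (1.8e-05), but not with the block without the trend (0.257). The count of genes past limma's threshold was 0 without a block, and 0 to 1 when each array was left out. With the replicate block it was 1995, 898 after quantile normalization, 688 after loess, 664 in the authors' table and 1321 with normexp, of which 853, 674, 661 and 1275 were among the 1995. Genes 1.5-fold apart within both slides numbered 732, against 147 with normexp and 1099 with no filter on dim probes, and 119 were 2-fold apart. Lists past the threshold numbered 18, against 10 after quantile normalization and in the authors' table, 11 after loess with or without the block, 17 among genes with a symbol (11 with loess as well), 13 to 18 when each array was left out, and 0 with an estimated correlation or by fry. With the block the postsynaptic list was the only call lost.

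Some lists changed direction, given here with their adjusted p. For glutamate receptors it was 0.6845 after quantile normalization, 0.6388 in the authors' table, 0.6823 after loess, 0.7265 by fry, 0.657, 0.6505 and 0.6751 for those 3 scalings with the block, and 0.8149 for loess among genes with a symbol. For ribosomal proteins it was 0.6845, 0.4527 and 0.004634 in the same order, 0.5618, 0.5037 and 0.001687 with the block, and 0.01618. For astrocytes it was 0.5962, 0.5938 and 0.5048, 0.9747 by fry, 0.4718, 0.4799 and 0.4861 with the block, and 0.598. By fry the inflammatory (0.664) and endothelial (0.7265) lists turned. When each array was left out, the lists that turned ranged as follows. The RNA-sensing list ran from 0.04684 to 0.3808 and oligodendrocytes from 0.003583 to 0.4555, both turning without shCTL replicate 1 or shCM1 replicate 2, and interferon-stimulated genes from 0.01615 to 0.9671, turning without shCTL replicate 1. The inflammatory list (0.1 to 0.9583), GABA signalling (0.005237 to 0.9583) and astrocytes (0.00102 to 0.09229) turned without shCTL replicate 2 or shCM1 replicate 1. Endothelial markers (0.2409 to 0.9583) turned without shCTL replicate 2, and the stress (8.387e-06 to 0.7355) and progenitor (7.476e-12 to 0.7575) lists without shCM1 replicate 1. In these fits without a block, leaving out shCTL replicate 1 or shCM1 replicate 2 weights shCM1 toward slide 1. Leaving out shCTL replicate 2 or shCM1 replicate 1 weights it toward slide 2. The turns of lists when an array is left out therefore take in the slide difference. For the other turns the reason was not tested.

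Single genes also turned, given here as log2 differences. With normexp, with or without the block, Cd74 was at 0.002 and Slc17a7 at 0.012. With the mean of a gene's probes Camk2b was at 0.032 and Acat2 at 0.049, and a single Camk2b probe was at 0.342. When each array was left out, C1qb ranged from -0.724 to 0.605, Cd74 from -0.429 to 0.363, Slc17a7 from -0.098 to 0.088, Neurod2 from -0.013 to 0.285 and Rig1 from -0.056 to 0.323. Rps26 ranged from -1.496 to 0.522, H2bc12 from -1.148 to 0.318, Hist1h4m from -0.935 to 0.13, Srxn1 from -0.089 to 1.487, Pdgfrb from -0.104 to 1.344 and Hes5 from -0.27 to 1.974. Leaving out an array also leaves the slides unequal between the groups, and for the rest the cause was not tested. Signals near background limit dim genes.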

Other observations

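All the tests of explanations here were chosen after the result they bear on had been seen. The genes in this paragraph were chosen after their values were seen, among those past the slide-blocked limma fit, and all values are log2 differences of shCM1 minus shCTL. They are single genes, and no list was tested for what they share. Among them Scd2, a fatty acid desaturase, was lower with -1.01 (SE 0.14), and Gpam, a mitochondrial acyltransferase, with -0.91 (SE 0.16). The kinases Tnik (-1.04, SE 0.15) and Ptk2b (-0.98, SE 0.18) and the cyclin Ccnd1 (-1.12, SE 0.42) were lower too. These values are of the brightest probe, and other probes had -0.25 for Gpam and -0.08 and -0.04 for Tnik. The neuropeptide genes Grp (-1.17, SE 0.20) and Crh (-1.23, SE 0.75) were lower, and Pdyn (0.59 in the blocked fit) was higher. With normexp Crh had -0.72 and Isl1 0.48. The transcription factors Pbx3 (0.72, SE 0.25), Foxp2 (0.63 in the blocked fit), Isl1 (0.75) and Meis2 (0.29) and the growth factor Igf1 (0.84, SE 0.37) were higher. Other probes of Igf1 had 0.94, 0.80, 0.04 and 0.54. Crh had -0.54 without shCTL replicate 1. Crh had -1.91, Pbx3 0.48 and Foxp2 0.40 without shCTL replicate 2. Ccnd1 had -0.52, Crh -2.20, Pdyn 0.38, Pbx3 0.46, Foxp2 0.32, Meis2 0.19 and Igf1 0.35 without shCM1 replicate 1. Ccnd1 had -1.72, Crh -0.26 and Igf1 1.33 without shCM1 replicate 2. After cyclic loess with the block Isl1 no longer passed, with an adjusted limma p of 0.0523, while the others named here did.

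Microglial markers were higher in the shCM1 array of both slides. A shift that depends on brightness is argued against, since 0 of 10000 lists matched on brightness had as high a median within either slide. A smaller share of neurons would raise astrocyte markers alike. As the only cause it is argued against, within these arrays, by a microglial median 0.674 above the astrocyte median. The 95% bootstrap interval over genes, 0.32 to 0.973, shows the spread among markers and not that between cultures. Oligodendrocyte, fibroblast and endothelial lists had medians of 0.164, 0.229 and 0.074, so a smaller share of neurons as a part of the rise stays open. Part of the 0.674 goes with brightness, as matched lists had medians of 0.134 for microglia and -0.014 for astrocytes. The markers did not move alike, with a heterogeneity Q of 48.4 against a limit of 26.3. That limit takes the standard errors as known, though each rests on few arrays. Probes of 1 marker can also differ, as for Tyrobp (0.97 and 0.41), and markers also expressed by other cells would move less. This spread therefore cannot decide on a larger number of microglia with unaltered expression per cell. A change in the number of microglia, in their state or in both stays open. Both groups were infected with a lentivirus, and an effect of CMTR1 loss was not separated from one of the shRNA itself.

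Inhibitory neuron markers were shifted upward against excitatory markers, by a difference of medians of 0.562 on slide 1 and 0.38 on slide 2. None (0) of 10000 pairs of brightness-matched lists differed by as much on either slide, which argues against a shift that depends on brightness. Excitatory markers did not move alike, with a heterogeneity Q of 60.6 against a limit of 22.4. They ran from -0.98 for Camk2a to 0.48 for Bcl11b. The limit takes the standard errors as known, Camk2a had -0.26 by its other probe, and Bcl11b is also expressed in interneurons. This spread therefore cannot decide on fewer excitatory neurons with unaltered expression per cell. What stays open is altered expression in inhibitory or excitatory neurons, a change in the makeup of the cultures among neuron types, or differences between the cultures on each slide. Averaged over the slides, the excitatory median alone did not stand apart from brightness-matched lists (adjusted share 0.898). The inhibitory median of 0.397 did, against a matched median of -0.021 (adjusted share 0.00128).

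Dim genes were higher in the shCM1 array of both slides, and the 10 spike-in RNAs, which are added to each labelling reaction, were used to ask whether this may be technical. Set against the other 7, the 3 dimmest spike-ins stood higher by medians of 0.304 on slide 1 and 0.19 on slide 2. Genes of the same ranges had 0.234 and 0.17. On slide 1 the 3 differed by 0.45, 0.2 and 0.44, against 0.1 to 0.16 for the brighter 7. On slide 2 they differed by -0.08, 0.33 and -0.08, against -0.31 to -0.26, so not all of them were higher in shCM1 there. A technical shift of dim signals relative to brighter ones may account for that part, though this rests on 3 spike-ins. Over the 10 spike-ins the mean difference correlated with level at a Pearson r of -0.79 and a Spearman rho of -0.71 (permutation p = 0.0088, 1 relation tested, r = -0.77 without the 2 farthest spike-ins). Over the range of the 7 brighter spike-ins the genes' slope on slide 1 was -0.023, outside the 95% interval of the spike-ins' slope (-0.0101 to 0.0046), as on slide 2, so a shift shared with the spike-ins is argued against there, while differences that arise before labelling and expression itself stay open.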
